A study of Danio rerio with 16 samples.

How the data were processed

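Total RNA profiles of 16 zebrafish (Danio rerio) samples were read on 1-colour Affymetrix arrays, with 1 value per probe set and array. The values are deposited as intensity on a linear scale, and in every array they had been scaled by the authors so that the 2% trimmed mean was the same (150.0 units), a property found from the values themselves. The software and the method that summarised the probes of a probe set are not given in the sources used here. The scaling removes differences in total brightness between arrays but not differences in the shape of their distributions, and array medians ranged from 46.2 to 66.0 units. Sequencing depth does not apply to arrays, and the number of arrays limits the precision. Signal close to background limits dim genes, since the 17 unused tag control probe sets reached up to 34.4 units.

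Each array was assigned to its group by its label, giving 4 wild-type and 6 foggy mutant samples at the stage labelled 36 h and 3 control RNA and 3 Foggy(DelCter) RNA samples at the 12-somite stage. The source field of every sample names brain and adrenal medulla, while the descriptions give embryonic brain for the 36 h samples and injected embryos for the others, and the descriptions were followed. Of 15617 probe sets, 115 controls were left out. Gene names came from the platform annotation given with the data, in which 10795 of the 15502 remaining probe sets had 1 gene symbol, 135 had several and 4572 had none. No gene was named from a probe set with several symbols. Symbols were updated through the Entrez gene number in a RefSeq table of assembly GRCz12tu, used for names only, which changed 1 symbol and left 8793 distinct symbols.

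The following choices were made before the data were examined: the groups, the tests, the filter, the gene lists, the rule for named genes and most of the other settings tried. Values were taken as log2(value + 16), so that log2 differences understate the change of dim genes. Arrays were used as deposited unless the log2 medians within a comparison differed by over 0.2. They differed by 0.373 among the 36 h arrays, which were quantile normalized, and by 0.103 among the 12-somite arrays, which were not. Probe sets whose mean fell below the 30th percentile of a comparison were left out, leaving 10851. Each comparison was fitted on its own with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with 2-sided moderated tests and Benjamini-Hochberg adjustment, and a probe set was called at an adjusted p under 0.05. The difference between the 2 comparisons was tested as a contrast in 1 fit over all 4 groups. Calls in both were compared with the product of the list sizes over the number tested and with a 2-sided Fisher exact test.

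The 25 gene lists were tested with camera at a preset correlation of 0.01, on the brightest probe set of each symbol and for lists with at least 5 measured members. Camera with an estimated correlation and fry were alternatives. The lists covered transcription elongation, immediate early genes, heat shock, p53 targets, cell cycle, ribosomal proteins, Hox genes, mitochondrial respiration, signalling feedback, inflammation, histones, monoaminergic neurons and 13 tissues or cell types. S6 kinases and rps19bp1, which match the naming pattern of ribosomal proteins, were dropped from that list once the matched names had been seen. Genes were named by rule. The first part took supt5h and each called elongation gene. The second took the 10 largest rises and 10 largest falls among called probe sets whose groups did not overlap and that had 1 symbol other than a clone name, a separation that chance alone gives 10% of the time with 3 against 3. The third took the 4 called members of each called list with the smallest p, or the 2 members with the smallest p where none was called. The fourth took the 5 genes called in both comparisons in the same direction and the 5 in opposite directions whose smaller change was largest. Other list members are named where they were called, and a few genes outside the rule, such as matn1, fkbp5, apoa1a and sncb, were chosen after their values were seen.

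The other settings fixed in advance were the other normalization, no filter, a filter at the 60th percentile, pseudocounts of 1 and 64, an intensity trend with a robust prior, 1 fit over all 4 groups, only the numbers that both groups share, the replicate number as a block, and each array left out in turn. After the split of the 36 h arrays by label number was seen, the array set as a block, numbers 4 to 6 alone and a genotype effect within each set were added. The labels share replicate numbers between groups, and deviations from the group means were correlated to check the pairing. Same-numbered 36 h arrays had r of 0.920, 0.761, 0.796 and 0.672 for numbers 1, 4, 5 and 6, and 0.0594, 0.281 and 0.355 within numbers 4 to 6. Same-numbered 12-somite arrays had r of 0.237, 0.230 and 0.181. Every pair but that of number 4 within numbers 4 to 6 exceeded 0.1, so the numbers were treated as pairing the samples. This pairing comes from these values alone and, at 36 h, follows the array sets. Wild type 4 matched mutant 5 better than mutant 4, with r of 0.787, and 0.191 within numbers 4 to 6. The pairing of number 4 is therefore uncertain.

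The fits were tested on simulated data with the real probe-set means and 200 of 10851 probe sets changed, 50 for each size and direction. In the fit of all 10 arrays 22 of the rises by 1 log2 unit and 44 of those by 2 were recovered, and 19 and 22 of the falls, with 24 of the larger falls below the filter and 0 unchanged probe sets called. With the set as a block 49 and 50 rises and 42 and 30 falls were recovered, with 11 unchanged probe sets called. In numbers 4 to 6 the counts were 39 and 49 rises and 34 and 35 falls, with 6 unchanged called, and in the injection comparison 44 and 50 rises and 37 and 38 falls, with 6 unchanged called. A list shifted by 0.5 was called in each fit, and 0 of 24 unchanged lists were. The noise was drawn independently for each probe set and the lists were random genes. Genes that vary together, as in the real lists, were therefore not simulated, and false calls of such lists were not tested. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.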

Results

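RNA abundance was measured with a zebrafish Affymetrix expression array in 16 samples that fall into 4 groups. Wild-type embryos (4 arrays) and embryos labelled as foggy mutants (6 arrays) were sampled at the stage labelled 36 h, with the material given as embryonic brain. Embryos at the 12-somite stage had been injected with a control RNA (3 arrays) or with an RNA named Foggy(DelCter) (3 arrays). The foggy gene is supt5h, which encodes the large subunit of DSIF, a factor that binds RNA polymerase II and acts on transcript elongation. The first comparison asks which transcripts differ between mutant and wild-type embryos, and the second which transcripts differ after injection of the altered foggy RNA. Each array holds 15502 probe sets apart from 115 control probe sets, with array medians between 46.2 and 66.0 intensity units. The number of arrays and, for dim genes, signal close to background limit the precision, and the labels do not say whether the replicates came from separate clutches, so the p-values measure the spread between these samples, which may be technical.

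The 10 brain arrays formed 2 sets that followed the numbers in their labels. Arrays numbered 1 to 3 (1 wild type and 3 labelled mutant) correlated with each other at r of 0.984 to 0.992 across probe sets, and arrays numbered 4 to 6 (3 and 3) at 0.957 to 0.992. Between the sets r was 0.831 to 0.872 (median 0.851), against 0.863 to 0.930 (median 0.909) between numbers 4 to 6 and the 12-somite arrays; these correlations run across probe sets, which are not independent replicates. Of the 25 gene lists, the endoderm, liver and yolk layer list had the largest median difference between the sets. Among arrays labelled mutant, 24 of the 26 measured members were lower in numbers 1 to 3 than in numbers 4 to 6, with a median log2 difference of -4.60 (camera adjusted p = 1.2e-12, and 0.00404 with an estimated correlation). The apolipoprotein transcript apoa1a had a mean intensity of 35.0 ± 3.89 (SD, n = 4) in the first set and 11361 ± 893 (n = 6) in the second. Of 33 Hox genes 28 were lower in numbers 1 to 3 and 2 higher, with a median of -1.84, and hoxc8a measured 7.03 ± 2.84 against 541 ± 128. Neuronal differentiation genes were higher there, 28 of 29, with a median of 3.21, and the synuclein transcript sncb measured 3048 ± 234 against 368 ± 131. The Hox and neuronal lists had an adjusted p = 0.0675 with an estimated correlation. In all, 7657 of 10851 tested probe sets (70.6%) differed between the mutant arrays of the 2 sets. The 3'/5' log2 ratio of the GAPDH control, a sign of RNA integrity, was 0.82 to 0.95 in numbers 1 to 3 and 0.49 to 0.78 in numbers 4 to 6. Genotype is therefore compared over all 10 arrays as designed, with the set as a block, and within each set, the last 3 having been chosen after seeing the data.

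**Figure D1:**
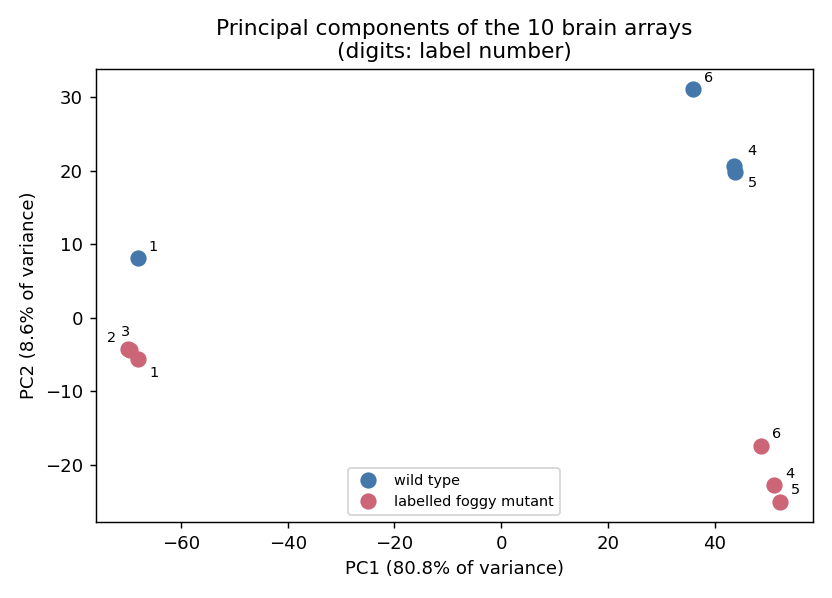
First and second principal components of the 10 brain arrays after quantile normalization, in component units, with wild-type arrays in blue, arrays labelled mutant in red, and each point marked with its label number. The first component (80.8% of the variance) parts numbers 1 to 3 from numbers 4 to 6, and on the second (8.6%) wild-type arrays lie above those labelled mutant within each set.

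The targeted gene, supt5h, was read by 1 probe set. In numbers 4 to 6, supt5h measured 198 ± 32.5 intensity units (SD, n = 3) in the wild type and 41.9 ± 4.51 (n = 3) in arrays labelled mutant, a log2 difference of -1.85 ± 0.14 (SE, limma adjusted p = 6.14e-05). The 17 unused tag control probe sets, a measure of background, reached at most 26.9 units in those mutant arrays. In numbers 1 to 3, supt5h measured 210 in the single wild-type array and 252 ± 6.91 (n = 3) in arrays labelled mutant. The log2 difference was 0.26 ± 0.16 (SE). Those 3 arrays thus lack the drop seen in numbers 4 to 6, which by itself does not contradict their label. Because their genotype rests on the label alone, "arrays labelled mutant" is used, and "mutant" for an array means its label. The effect on supt5h differed between the sets by -1.99 ± 0.20 (adjusted p = 0.000485). Over all 10 arrays the difference was -0.73 ± 0.52 (adjusted p = 0.775). With the set as a block it was -1.07 ± 0.28 (adjusted p = 0.0277), and with the replicate block it was -1.26 (adjusted p = 0.0387). The labels name no allele, and where the probe set lies relative to the mutation is not given in the sources used here. At the 12-somite stage supt5h measured 409 ± 23.9 (n = 3) in control and 428 ± 43.6 (n = 3) in Foggy(DelCter) samples, a log2 difference of 0.06 ± 0.12 (adjusted p = 0.802). Whether the probe set reads the injected RNA is not given either, so its level there checks nothing about the injection.

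**Figure D2:**
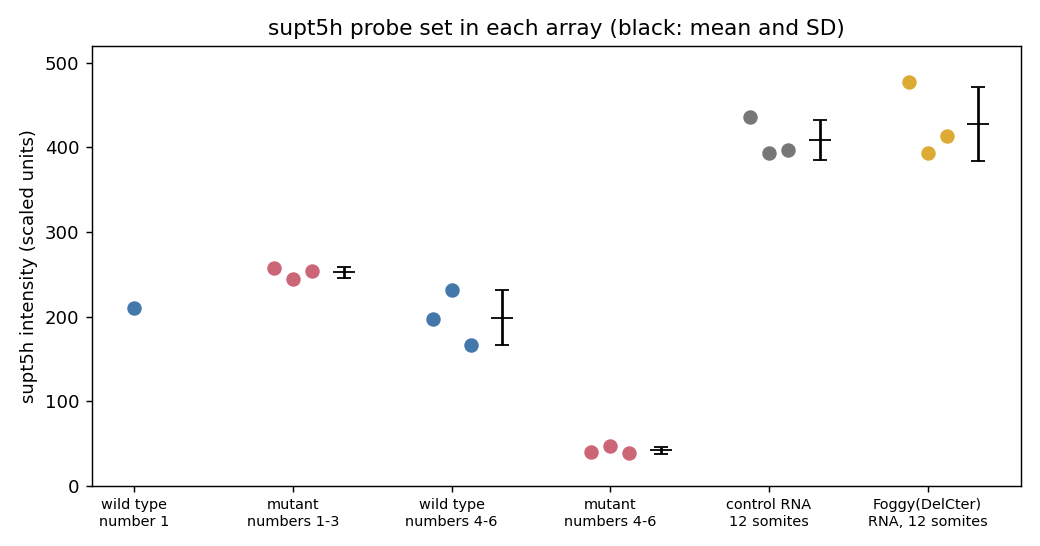
Intensity of the supt5h probe set in each array (points, scaled units, linear axis from 0), by group and label number, with the mean and SD of each group of 3 in black. Arrays labelled mutant lie at 38.6 to 47.0 in numbers 4 to 6 and at 245 to 258 in numbers 1 to 3.

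Over all 10 brain arrays, the arrays labelled mutant had lower transcripts of heart muscle and red blood cells than the wild type, with 3 of the 6 showing no lower supt5h. With an estimated correlation the heart muscle list kept an adjusted p of 0.0272 and the blood list had 0.0837. The cardiac myosin light chain genes myl7 and cmlc1 had log2 differences of -2.65 ± 0.16 and -2.31 ± 0.26 (SE, 6 against 4 arrays). Among red blood cell genes, the anion exchanger slc4a1a (-3.10 ± 0.37), the haem synthesis enzyme alas2 (-1.91 ± 0.23), the carbonic anhydrase cahz (-1.96 ± 0.30) and the globin hbae3 (-1.86 ± 0.25) fell. The mutant mean of slc4a1a, 23.0 units, lay within the range of the tag controls, as did that of slc2a15b below, so the size of these falls is not set (at least 9.50-fold and 2.80-fold against the highest tag control). The muscle calcium buffer pvalb1 fell by 3.09 ± 0.47. Hexim1, an inhibitor of the elongation kinase P-TEFb, rose by 0.62 ± 0.09, as did the kinase mknk2b by 0.69 ± 0.10 and natd1 by 0.70 ± 0.11. Further falls were those of the sodium pump subunit atp1b1b (-1.69), the sugar transporter family member slc2a15b (-1.64) and the cartilage collagen col9a1b (-1.63). In all 24 probe sets were called, 4 higher and 20 lower, of 10851 tested, at limma adjusted p-values from 0.000132 for myl7 upward. The replicate block, over numbers 1, 4, 5 and 6, called 393 higher and 640 lower, and the set block 651 higher and 774 lower, and all 24 were among both. The 1425 calls with the set block became 685, 762 and 835 without wild type 4, 5 or 6 and 719, 743 and 932 without mutant 4, 5 or 6. In the fit without a block, without wild type 1, 270 were called, without wild type 4 or wild type 5 1 each, without wild type 6 3, and without 1 of the mutant arrays 7 to 16.

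Of the 25 gene lists, 9 moved in this comparison over all 10 arrays by camera, 8 down and 1 up. Of the 5 measured heart muscle genes 2 fell and 3 did not pass, with a median of -0.83 (adjusted p = 6.84e-06, and 0.0272 with an estimated correlation). Of 21 blood genes 4 fell and 17 did not pass, and 11 fell adjusted over the list alone (adjusted p = 1.06e-14, and 0.0837 with an estimated correlation). Of 36 skeletal muscle genes pvalb1 alone fell, and 10 fell adjusted over the list alone (adjusted p = 1.05e-15, and 0.237 with an estimated correlation). The median of that list was -1.27, and -0.80 with the set as a block, numbers 1 to 3 holding 3 of the 6 arrays labelled mutant and 1 of the 4 wild-type arrays. Of 41 cell cycle genes and 46 neural progenitor and Notch genes none passed limma's test singly, with 9 and 2 falling adjusted over the list alone and 14 and 9 at an unadjusted p under 0.05. Their smallest p-values belonged to rrm1 (-0.83 ± 0.15, adjusted p = 0.0879), mcm5 (-0.97 ± 0.20, adjusted p = 0.104), dlc (-1.73 ± 0.30, adjusted p = 0.0701) and jag1b (-0.54 ± 0.11, adjusted p = 0.111). Both lists had an adjusted p = 0.237 with an estimated correlation. Of 11 pigment cell genes 4 fell adjusted over the list alone (adjusted p = 3.41e-05, and 0.209 with an estimated correlation). The transcription elongation list shifted up with a median of 0.17, hexim1 being its 1 called gene of 31 (adjusted p = 0.00467, and 0.237 with an estimated correlation). The small endothelium list (adjusted p = 0.0349, 0.0694 with the values as deposited, and 0.624 with an estimated correlation) held kdrl at -0.60 ± 0.16 and plvapb at -0.72 ± 0.28, neither passing. The Hox list was lower over all 10 arrays (adjusted p = 0.031, and 0.813 with an estimated correlation), where hoxa5a (-0.25 ± 0.15) and hoxa3a (-0.29 ± 0.23) did not pass, and it turned to higher within numbers 4 to 6. With the replicate block 19 lists were called, among them all of these but the Hox list (adjusted p = 0.0626, upward), which was not called in those arrays without a block either.

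Within numbers 4 to 6, where supt5h was low, the muscle, blood, pigment, neuronal, eye, crest and cell cycle lists shifted down in the arrays labelled mutant, with some members of the eye, crest and cell cycle lists higher. With an estimated correlation no list passed there, the lowest adjusted p being 0.0792. Among the largest falls were gch2, the GTP cyclohydrolase of pteridine pigment synthesis (-5.84 ± 0.23, SE, 3 against 3). Others were the sodium pump subunit atp1a1a.2 (-4.01 ± 0.16), slc4a1a (-3.84 ± 0.33), the fast muscle genes tnni2a.4 (-3.84 ± 0.47), pvalb1 (-3.72 ± 0.58), tnnt3b (-3.58 ± 0.58), myhz1.3 (-3.53 ± 0.24) and mylpfa (-3.19 ± 0.26), the lens crystallin crybb1 (-3.35 ± 0.16) and the myeloid lysozyme lyz (-3.29 ± 0.27). The mutant means of gch2 (7.69 units), atp1a1a.2 (24.8), slc4a1a (10.5), crybb1 (14.1) and lyz (6.80) lay within the range of the tag controls, so the size and order of those falls are not set. With the highest tag control in place of the mutant mean they are at least 50.9-fold, 24.3-fold, 14.2-fold, 10.9-fold and 7.96-fold. Sizes are likewise not set for the falls of dct, slc2a15b, mitfa, cmlc1, sptb, cryba4, dlc, neurod6b, ins and ret and for the rise of gadd45aa below, among 168 such called probe sets with a symbol. The largest rises were foxd5 (1.74 ± 0.12), the AP-1 subunit fosab (1.48 ± 0.28), rasd1 (1.47 ± 0.11), zp2.6 (1.32 ± 0.32), gadd45ba (1.31 ± 0.12), the surface glycoprotein gene tpbg1b (2.46-fold), gadd45ga (1.29 ± 0.14), hsp70.3 (1.28 ± 0.14), plekhf1 (1.24 ± 0.13) and cyp11a1.1 (1.18 ± 0.22). The probe set of hsp70.3 also matches other transcripts by its design, so that value is uncertain among the near-identical heat shock genes. Limma called 2119 probe sets, 990 higher and 1129 lower, and of those at least 2-fold 47 were higher and 265 lower. This fit was added after seeing the data, and leaving out wild type 4, wild type 5, mutant 4 or mutant 5 lowered the calls to 1186, 1274, 1250 and 1167.

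Camera called 20 of the 25 lists within numbers 4 to 6, none of them with an estimated correlation. By fry, the other alternative, each of these lists but heat shock passed (fry adjusted p = 0.0507 for heat shock). Of 38 skeletal muscle genes 26 fell and 12 did not pass, and 28 fell and 1 rose adjusted over the list alone, with myl1 at -2.24 ± 0.16 and the calcium pump atp2a1 at -1.54 ± 0.13 (median -0.88, adjusted p = 0.127 with an estimated correlation). Heart muscle had 3 of 6 genes falling, myl7 at -3.04 ± 0.12, cmlc1 at -3.05 ± 0.13 and tnnt2a at -1.14 ± 0.20 (adjusted p = 0.13 with an estimated correlation). Of 22 blood genes 14 fell, 16 adjusted over the list alone, among them the haem enzyme urod at -1.98 ± 0.13 and the red cell spectrin sptb at -2.15 ± 0.18. In the endothelium list 5 of 6 fell, with kdrl at -0.95 ± 0.12 and fli1 at -1.11 ± 0.16. In pigment cells 7 of 11 fell, including the melanin enzyme dct at -3.07 ± 0.18, slc2a15b at -3.03 ± 0.15 and the melanocyte factor mitfa at -1.48 ± 0.13. In neural crest and head cartilage 11 of 29 fell and 3 rose, with crestin at -2.37 ± 0.15 and the collagen col2a1a at -1.28 ± 0.17. Of 10 eye genes 6 fell and 2 rose, the blue opsin opn1sw2 being higher (0.76 ± 0.14) and the lens crystallin cryba4 lower (-2.80 ± 0.33). The eye list had an adjusted p = 0.13 with an estimated correlation, and the blood, endothelium, pigment and crest lists 0.0792.

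In the nervous system lists of the same arrays, 19 of 26 neuronal differentiation genes fell, 20 adjusted over the list alone, and none rose. They included the growth cone protein gap43 (-1.22 ± 0.15), dpysl3 (-1.24 ± 0.11), the transcription factor neurod6b (-1.54 ± 0.19) and the glutamate transporter slc1a2b (-1.01 ± 0.11), whose value over all 10 arrays was 0.17. Slc1a2b is also a member of the glia list. Neural progenitor and Notch genes fell in 22 of 47 and rose in 1, with the Notch ligand dlc at -2.50 ± 0.12, the proneural factor neurog1 at -1.34 ± 0.13, sox11b at -1.84 ± 0.19 and her2 at -1.20 ± 0.13. The brightest probe set of sox11b, which the list count used, measured -0.91. In the glia list 8 of 17 fell and 1 rose, the falls including gja1b (-2.13 ± 0.19), vim (-1.11 ± 0.11) and olig3 (-0.82 ± 0.11). In the monoaminergic list 6 of 13 fell, namely the neuronal regulators otpb (-1.95 ± 0.27), ascl1a (-0.96 ± 0.12) and neurog1, together with gch2, ret and tfap2a. Gch2 is also a pigment list member, and the serotonin synthesis gene tph1a measured -0.18 ± 0.13 (adjusted p = 0.369). Cell cycle genes fell in 22 of 41 and rose in 2, led by the replication helicase subunits mcm2 (-1.52 ± 0.12), mcm5 (-1.43 ± 0.11) and mcm3 (-1.20 ± 0.11). Histone and chromatin genes fell in 10 of 35 and rose in 1, with hmgb3a at -1.73 ± 0.12 and nap1l1 at -1.29 ± 0.12. With an estimated correlation the adjusted p was 0.081 for the glia list and 0.0792 for the other lists of this paragraph.

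The immediate early, p53, elongation, Hox, mitochondrial and yolk lists shifted up within numbers 4 to 6, and the heat shock list was called lower, none of them with an estimated correlation. Immediate early genes rose in 10 of 24 and fell in 3, with jun at 0.91 ± 0.14 and myca at -0.92 ± 0.12 (adjusted p = 0.26 with an estimated correlation). The p53 and apoptosis list rose in 8 of 28 and fell in 1, 12 and 1 adjusted over the list alone, the rises including tp53inp1 (0.74 ± 0.11), pmaip1 (0.85 ± 0.14), rps27l (1.07 ± 0.19) and gadd45aa (0.69 ± 0.14) (adjusted p = 0.26 with an estimated correlation). In the elongation list 10 of 31 rose and 2 fell, supt5h itself and the FACT subunit ssrp1a (-0.62 ± 0.12). The rises there were hexim1 (0.71 ± 0.11), the cyclin ccnt2a (0.84 ± 0.17), the cap-binding ncbp2 (0.47 ± 0.12), ell (0.40 ± 0.11) and 6 RNA polymerase II subunits, led by polr2a (1.01 ± 0.20), polr2eb (0.72 ± 0.13) and polr2f (0.68 ± 0.12) (adjusted p = 0.32 with an estimated correlation). Heat shock and protein folding genes went both ways, 3 up and 7 down of 24, with the chaperones hsp90b1 at -1.05 ± 0.17 and hsp90aa1.1 at -0.91 ± 0.12 (adjusted p = 0.0468, 0.0756 with the values as deposited, and 0.246 with an estimated correlation). Hox genes rose in 13 of 38 and fell in none, among them hoxb10a (1.06 ± 0.12), hoxc5a (1.15 ± 0.15), hoxd10a (0.87 ± 0.11) and hoxb6a (0.81 ± 0.11). Over all 10 arrays hoxd10a was -0.21 and hoxb6a -0.35, and the Hox list had an adjusted p = 0.246 with an estimated correlation. Mitochondrial respiration genes rose in 25 of 80 and fell in 1, with ndufa1 at 0.69 ± 0.16 and uqcrq at 0.58 ± 0.12 (adjusted p = 0.111 with an estimated correlation). In the endoderm, liver and yolk list 5 of 28 rose and insulin, ins, fell (-0.92 ± 0.22), while prss1 was 0.74 ± 0.13, rbp2a 0.88 ± 0.11 and rbp4l 0.57 ± 0.13. The values of rbp2a and rbp4l over all 10 arrays were -0.37 and -0.54, and the list had an adjusted p = 0.0934 with an estimated correlation. The ribosomal protein, epidermis, somite, signalling feedback and inflammation lists were not called.

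Within numbers 1 to 3 the arrays labelled mutant had lower muscle and red blood cell transcripts than the single wild-type array, so a difference of genotype and one of that array alone are not separated. The actin control's 3'/5' log2 ratio was 3.13 in wild type 1 and 1.51 to 1.78 in the arrays labelled mutant 1 to 3. Its probe sets are named for acta1, a skeletal muscle actin. Muscle transcripts were lower in those arrays too, but whether the ratio follows muscle level or RNA integrity was not tested. In numbers 4 to 6, where muscle transcripts also fell, the ratio was not lower in arrays labelled mutant (2.32 to 2.51) than in the wild type (2.05 to 2.44). A difference in RNA quality of wild type 1 is therefore not separated from the effects below either. Of 10851 probe sets 6 were higher and 73 lower, in a fit that assumes that the lone wild-type array varies like the other groups. These included myl7 (-2.14 ± 0.18), cmlc1 (-1.36 ± 0.15), the muscle actin actc1b (-1.68 ± 0.15), the slow myosin smyhc1 (-1.45 ± 0.17), alas2 (-1.55 ± 0.19) and the globin hbbe3 (-1.95 ± 0.24). In the eye list 6 of 18 fell, including the ultraviolet opsin opn1sw1 (-1.66 ± 0.22), opn1sw2 (-1.07 ± 0.17) and the lens filament gene bfsp2 (-1.41 ± 0.21). Camera called 7 lists there, none of them with an estimated correlation. The adjusted p was 1.35e-12 for skeletal muscle (0.212 with an estimated correlation), 8.04e-11 for blood (0.0959), 2.54e-05 for the eye list (0.126) and 5.91e-06 for heart muscle (0.0772). The pigment and Hox lists were also lower and the elongation list higher, with an adjusted p = 0.0959, 0.202 and 0.304 with an estimated correlation. The cartilage matrix gene matn1 (-2.35 ± 0.18), fkbp5 (-2.47 ± 0.19) and dhrs13a.2 (-1.76 ± 0.14) shared the smallest adjusted p, 0.000102. Polr2a was higher by 1.42 ± 0.23 at another of its probe sets (adjusted p = 0.0176), and hexim1 measured 0.58 ± 0.13 (adjusted p = 0.0891). In the progenitor and cell cycle lists, with medians of 0.04 and 0.02, and in the neuronal list, no gene passed by limma, with 5, 2 and 3 genes at an unadjusted p under 0.05. Between the sets the effect differed for 357 probe sets, 98 higher and 259 lower in numbers 4 to 6, among them gch2, limited by background in size (-4.28 ± 0.36), crestin (-2.19 ± 0.25), dpysl3 (-1.18 ± 0.15), mcm3 (-1.21 ± 0.15) and foxd5 (2.01 ± 0.18). It was not shown to differ for hexim1 (0.11 ± 0.16) or alas2 (-0.30 ± 0.23). Of 2059 probe sets called in numbers 4 to 6 and tested in both, 1328 (64.5%) had the same sign in numbers 1 to 3.

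**Figure D3:**
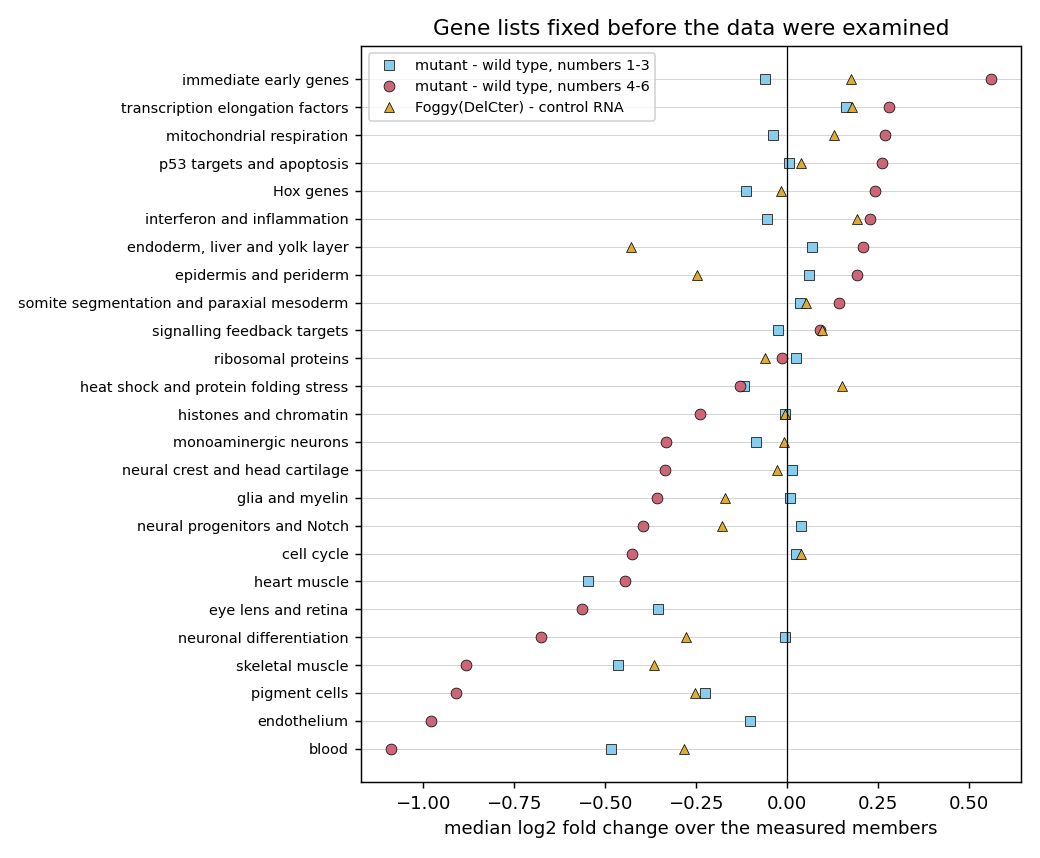
Median log2 fold change of the measured members of each of the 25 gene lists, as squares for arrays labelled mutant against wild type in numbers 1 to 3, circles for the same in numbers 4 to 6, and triangles for Foggy(DelCter) against control RNA (22 lists with at least 5 measured members). Blood and skeletal muscle lie below 0 in all 3, and neuronal differentiation lies at -0.67 in numbers 4 to 6 and near 0 in numbers 1 to 3.

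Embryos injected with Foggy(DelCter) RNA had higher heat shock transcripts and lower liver, yolk, skeletal muscle and neuronal transcripts than embryos injected with control RNA at the 12-somite stage. With an estimated correlation the adjusted p was 0.192 for the heat shock and neuronal lists, 0.204 for skeletal muscle and 0.344 for liver and yolk, and in 1 fit over all 4 groups none of these 4 lists was called. The 3'/5' log2 ratio of the actin control was 2.81 to 3.14 in control and 2.21 to 2.81 in injected samples, and that of the GAPDH control averaged 0.40 and 0.60. The actin control is a skeletal muscle actin, and muscle transcripts were lower after injection. Whether its ratio follows muscle level or RNA integrity was not tested. All 3 measured heart muscle genes were higher after injection at an unadjusted p under 0.05. The largest rise was hsp70.3 (2.51 ± 0.12, log2, SE, 3 against 3), whose probe set may read several near-identical genes. It was followed by ptgdsb.2 (2.14 ± 0.13), the nuclear receptor hnf4a (1.73 ± 0.12), the water channel aqp3a (1.56 ± 0.13), the chaperone hspa8b (1.50 ± 0.17), the mitotic kinesin kif20a (1.49 ± 0.15), ptgdsb.1 (2.47-fold), tpbg1b (1.24 ± 0.12), the secreted regulator szl (1.14 ± 0.18) and socs3a (1.14 ± 0.13). The largest falls were the apolipoprotein apoba (-2.33 ± 0.13), bhmt (-2.07 ± 0.14), anxa6 (-2.07 ± 0.20), epb41l3b (-2.03 ± 0.15), plasminogen, plg (-1.94 ± 0.14), nt5c3a (-1.78 ± 0.12), apoa4a (-1.70 ± 0.13), the tau gene maptb (-1.60 ± 0.16), fabp2 (-1.55 ± 0.13) and the muscle tropomodulin tmod4 (-1.54 ± 0.12). The dimmer group's mean for aqp3a, hspa8b, socs3a and plg lay within the range of the tag controls, up to 23.9 units in control and 18.9 in injected samples, so the size of those differences is not set (at least 2.13-fold, 2.59-fold, 2.83-fold and 4.84-fold). Limma called 1223 probe sets of 10851, 404 higher and 819 lower, 37 and 93 of them by at least 2-fold. The log2 medians of the arrays were 6.04 to 6.07 in control and 5.97 to 5.99 in injected samples. With quantile normalization 438 were called higher and 640 lower, so part of the excess of falls depends on the scaling. A single fit over all 4 groups called 23 and 31, and no filter on dim probe sets 228 and 522. Without control 1 or 3, 801 and 597 were called, and without injected sample 2 or 3, 669 and 739.

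Camera called 9 of the 22 measured lists in the injection comparison, and none with an estimated correlation. Fry, the other alternative, called 13 lists, but not the signalling feedback and mitochondrial lists that camera called. In the endoderm, liver and yolk layer list 11 of 25 fell and 4 rose, 14 and 7 adjusted over the list alone, with apobb.1 at -1.24 ± 0.14 and transferrin, tfa, at -1.24 ± 0.13 (adjusted p = 0.0036, and 0.344 with an estimated correlation). Of 24 skeletal muscle genes 8 fell and 1 rose, with acta1a at -0.94 ± 0.14, actc1b at -1.19 ± 0.18, smyhc1 at -1.12 ± 0.17 and the myogenic factor myog at -0.85 ± 0.15 (adjusted p = 0.204 with an estimated correlation). Neuronal differentiation genes fell in 5 of 15, including nrp1a (-0.94 ± 0.14) and the RNA-binding elavl3 (-0.71 ± 0.13). Progenitor and Notch genes fell in 8 of 45 and rose in 3, with six3a at -0.89 ± 0.13 and pax2a at -0.65 ± 0.14 against dlx2a at 0.71 ± 0.12 and hes6 at 0.62 ± 0.13. Epidermis genes fell in 4 of 26, such as anxa1c (-0.80 ± 0.12) and krt97 (-0.59 ± 0.11) (adjusted p = 0.344 with an estimated correlation). Heat shock genes rose in 5 of 25, and 8 rose and 1 fell adjusted over the list alone, with hsp90aa1.2 at 0.85 ± 0.12, dnajb1b at 0.67 ± 0.17 and hspe1 at 0.55 ± 0.12. Elongation genes rose in 4 of 31, hexim1 (0.92 ± 0.18), polr2a (0.57 ± 0.13), polr2i (0.55 ± 0.12) and polr2f (0.48 ± 0.12). The neuronal, progenitor, heat shock and elongation lists had an adjusted p = 0.192 with an estimated correlation. Signalling feedback genes rose in 6 of 38 and fell in 2, with bmp2b at 0.73 ± 0.14 and gli3 at -0.75 ± 0.12, and mitochondrial genes rose in 5 of 77, such as cox5aa (0.48 ± 0.12). For both of these lists the adjusted p was 0.344 with an estimated correlation. No p53 target or ribosomal protein gene passed by limma, with 4 and 1 at an unadjusted p under 0.05.

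Between the 2 comparisons, which share no control arrays, the called genes went the same way more often than independent lists would. With the mutant effect taken from numbers 4 to 6, 107 probe sets were higher in both against 34.6 for independent lists, and 173 were lower in both against 73.4 (2-sided Fisher exact p = 4.61e-28 and 4.19e-29, with probe sets that are not independent). In the opposite directions, 46 and 22 were found against 75.8 and 33.5. Shared rises included hsp70.3, tpbg1b and hexim1, and shared falls the muscle actin actc1b (-1.26 and -1.11), the globin hbae3 (-1.60 and -1.09) and the matrix protein dcn (-1.80, and at least 2.45-fold lower after injection, where it lay within the tag control range). In the injection aqp3a is limited in the same way. The actc1b and hbae3 probe sets used here also match other transcripts by their design, and they are not those of the values given above. Genes with opposite effects included aqp3a (-3.07 in the mutant and 1.56 after injection), cyp11a1.1 (1.18 and -1.08), the complement gene c7b (1.06 and -1.35), rbp2a (0.88 and -0.93) and the keratin krt99 (1.04 and -0.76). From all 10 brain arrays 8 probe sets were shared, 2 higher and 6 lower in both, including hexim1, mknk2b, meis3, hbae3 and col9a1b, and none had opposite effects. The correlation across probe sets was 0.32 with all 10 arrays and 0.23 with numbers 4 to 6. The effects differed between the comparisons for 8 probe sets in the fit with all brain arrays, among them xpr1b (1.11 ± 0.18) and ptgdsb.2 (-1.48 ± 0.24), and for 1120 without numbers 1 to 3. Of the 8, myl7 and slc4a1a were below the level filter at 12 somites, so their difference only repeats the mutant effect. These comparisons differ in stage and in the labelled material as well as in the treatment.

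**Figure D4:**
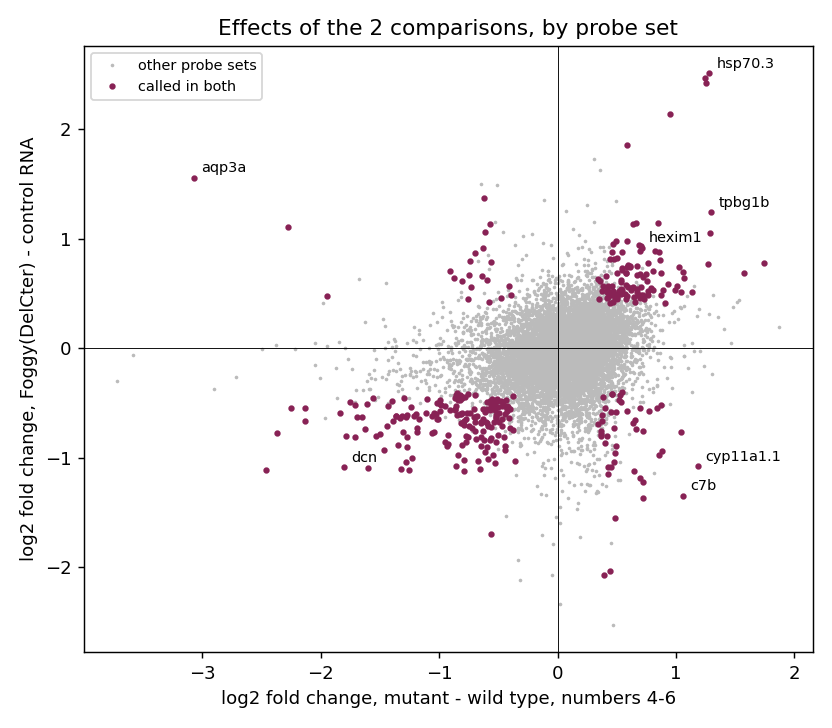
Log2 fold change of each probe set tested in both comparisons, for arrays labelled mutant against wild type in numbers 4 to 6 (horizontal) and Foggy(DelCter) against control RNA (vertical), with the 348 probe sets called in both in dark red. The 107 called higher in both and the 173 called lower in both outnumber the 68 with opposite signs.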

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

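All 4 tests that weigh an explanation in this part, on scaling, tissue makeup, supt5h signal and sample labels, were chosen only after the results they bear on were seen.

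In 6 of 52 groups of values checked, 1 array lay apart from the rest of its group by Dixon's ratio, the gap to the nearest array over the range of the group, and chance flags about 1 in 20 groups. For the anion exchanger slc4a1a, mutant array 4 was the lowest of 6 at 4.17 on the normalized log2 scale, on which all gene ratios here were taken, against 5.06 to 5.52 (ratio 0.662). Its 1.23 intensity units lie below the 7.40 median of the tag controls in that array, so it stands apart only below background. In wild-type array 6 the muscle gene pvalb1 measured 11.55 on that scale against 9.67 to 9.85 in the other 3 arrays (ratio 0.907), and the globin hbae3 measured 13.03 against 12.46 to 12.56 (ratio 0.830). Wild-type array 1 had the lowest mean of its group for the cell cycle list (0.870), the Hox list (0.880) and the heart muscle list (0.859), and it is the wild-type array that belongs to the set numbered 1 to 3. The effects of the mutant and the injection comparison differed for 8 probe sets in the fit of all 4 groups, among them myl7, slc4a1a, ptgdsb.2, xpr1b and si:dkey-260j18.2, with 3 probe sets that carry no symbol. For myl7 and slc4a1a, below the level filter at 12 somites, that difference only repeats the mutant effect.

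The brain arrays numbered 1 to 3 stood apart from those numbered 4 to 6. Different scaling of the sets is argued against, since rank correlations, which scaling cannot move, were at most 0.861 between the sets and at least 0.946 within them, while a different summary of the probes stays open and was not tested. Different tissue makeup of the 2 sets stays open, since the neuronal list was called higher and the Hox, skeletal muscle and yolk lists lower in numbers 1 to 3, 4 of 4 (adjusted p 0.0675, 0.0675, 0.384 and 0.00404 with an estimated correlation, the yolk list alone passing), but they were picked for it once seen and so test nothing. Those lists hold 36, 42, 39 and 35 genes, of which 2, 0, 2 and 2 are also in another list, and some abundant members differed between numbers 1 to 3 and 4 to 6 in mean intensity for apoa1a (35.0 and 11361), afp4 (15.2 and 10551), apoa2 (51.1 and 8814), actc1b (580 and 4773), hoxc8a (7.03 and 541), sncb (3048 and 368), stmn1b (2689 and 355) and tubb5 (2549 and 753), but hoxb3a (360 and 297), hoxb5a (116 and 172) and aldoaa (1971 and 2326) differed less. That numbers 1 to 3 hold brain with little trunk, liver and yolk and numbers 4 to 6 more of the embryo is thus a candidate explanation that those 4 lists do not test, and the labels describe no dissection and a difference in age between the sets was not tested.

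The level of supt5h was lower in the mutant arrays numbered 4 to 6 but not in those numbered 1 to 3, the effects differing by -1.99 on the log2 scale, and the mutant effect differed between the sets for 357 probe sets in all. A weaker supt5h signal in one array set is argued against, since the wild-type arrays of the sets differed by -0.045 while the drop in numbers 4 to 6 was -1.85. Arrays labelled mutant 1 to 3 made from wild-type embryos cannot be told apart from mutants correctly labelled, because the slope of the effects in numbers 1 to 3 on those in numbers 4 to 6 has 4 possible labellings and so no share under 0.05, and every measure of that effect rests on 1 wild-type array. That slope was 0.225 over 2059 probe sets with the real labelling, and 0.188 over the 1732 probe sets outside the gene lists. It was at most -0.07 with any other labelling. The slopes of the 4 labellings cancel out by construction, so the negative ones add no evidence. The positive slope goes the way of the labels, as do the 64.5% of the 2059 probe sets with the same sign. A different foggy allele or a mixture of genotypes in numbers 1 to 3, on which the labels are silent, stays open and was not tested.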

How the results depend on the processing

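The array set as a block, numbers 4 to 6 alone and their values as deposited were settings chosen only after the data were seen. Over all 10 brain arrays (4 probe sets higher, 20 lower) the counts were 1 and 5 with the values as deposited, 2 and 10 above the 60th percentile and 1 and 3 for numbers 1, 4, 5 and 6 without a block. They were 46 and 111 in 1 fit over all 4 groups, 393 and 640 with the replicate block, 651 and 774 with the set block, 990 and 1129 in numbers 4 to 6, and 882 and 1231 there as deposited. Leaving out 1 array gave 0 to 83 higher and 1 to 187 lower, the maximum without wild type 1 and the minimum without wild type 4 or 5. For the injection (404 higher, 819 lower) the counts were 228 and 522 without a filter and 23 and 31 in 1 fit over all 4 groups, with 268 higher at a pseudocount of 1, and 199 to 295 higher and 398 to 628 lower with 1 array left out. The 8 probe sets shared in direction became 4 without a filter, 4 at a pseudocount of 1, 5 in 1 fit, 0 with the other normalization, 208 with the replicate block in both, 233 with the set block, 280 in numbers 4 to 6 and 0 to 48 with 1 array left out. The 0 with opposite directions became 41, 40 and 68 with the replicate block, the set block and numbers 4 to 6, and 0 to 4 with 1 array left out. The 8 probe sets whose effects differed between the comparisons became 14 as deposited and 1120 in numbers 4 to 6 with the 12-somite arrays. The 9 lists called in the mutant became 17 for numbers 1, 4, 5 and 6 without a block, 19 with the replicate block, 19 with the set block, 20 in numbers 4 to 6, 19 there as deposited, 1 with an estimated correlation and 4 with fry. The 9 lists called after injection became 0 with an estimated correlation and 13 with fry. The supt5h difference (-0.73) passed at -1.26 with the replicate block, -1.07 with the set block, -1.85 in numbers 4 to 6 and -1.88 there as deposited. Signs turned for slc1a2b (0.17) to -0.75 with the replicate block, -0.66 with the set block, -1.01 in numbers 4 to 6 and -1.05 there as deposited, and for hoxd10a (-0.21) to 0.66, 0.55, 0.87 and 0.86. In numbers 4 to 6 and there as deposited they also turned for hoxb6a (-0.35, to 0.81 and 0.78), rbp2a (-0.37, to 0.88 and 0.89) and rbp4l (-0.54, to 0.57 and 0.58). Some of these settings hold fewer arrays or fewer probe sets by construction, and beyond that the cause was not tested. With the replicate block the injection comparison called 570 and 1033, with 1220 of the 1223 shared. The replicate block, which in the mutant also leaves out mutant arrays 2 and 3, ended the call of no named gene in either comparison, and 68 named genes gained a call there. Of the lists only Hox lost its call, and it was also lost in the same arrays without a block. Named genes kept their direction and side of the threshold in 600 gene-by-setting results after injection and 1782 in the mutant, lost the call in 116 and 106, and gained it in the mutant in 355. The heart muscle list kept its call in 23 of 23 settings, the Hox list in 10 of 24, the endothelium list in 16 of 23 and the injection's signalling list in 9 of 16. The lowest group mean of supt5h, 41.9 units, exceeded the highest tag control of those arrays, 26.9. The size of its difference over all 10 arrays still moved with the pseudocount, from -0.86 at 1 to -0.50 at 64.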

Other observations

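Among the tests in this part, those of slower development over all probe sets and of the listed tissues were chosen only after the result was seen. So were the fits with the set as a block and of numbers 4 to 6 alone whose splits are counted. Chosen before their results were the tests of normalization, of the falling cell cycle and progenitor genes and of the splits of all 10 brain arrays and of the injection. The tests of normalization and of the falling genes use numbers 4 to 6, however, which were set apart only after the data were seen.

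Several lists without a call held genes that moved in opposite directions. In numbers 4 to 6, 7 of 28 epidermis genes rose and 3 fell (adjusted p = 0.271), the keratin krt8 rising by 0.69 ± 0.11 (log2, SE, 3 against 3) and the basal keratinocyte factor tp63 falling (-0.86 ± 0.11). Of 22 somite genes 3 rose and 4 fell (adjusted p = 0.901, with a median of 0.14 and a mean of -0.05), the tail bud gene cdx4 rising (1.07 ± 0.23) and the Notch modifier lfng falling (-1.43 ± 0.16). Of 35 signalling feedback genes 5 rose and 4 fell (adjusted p = 0.93), with id3 at 0.96 ± 0.12, and ccnd1 at -0.92 ± 0.11. Of 18 inflammation genes 3 rose and 2 fell (adjusted p = 0.492), with socs3a at 0.85 ± 0.20 and the chemokine cxcl12b at -0.65 ± 0.12. Of 72 ribosomal protein genes 1 rose, rps27l, which is also a p53 target (adjusted p = 0.788).

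After injection of Foggy(DelCter) RNA, Hox genes went both ways, 4 of 36 rising and 4 falling (adjusted p = 0.927), with hoxb10a at 0.77 ± 0.18 and hoxd9a at 0.54 ± 0.14 against hoxa2b at -0.65 ± 0.15 and hoxa11b at -0.65 ± 0.19. In the glia list 6 of 16 fell and 2 rose (adjusted p = 0.13), including gfap (-0.66 ± 0.15) and the glutamate transporter slc1a3a (-0.76 ± 0.16). Of 16 blood genes 5 fell and 1 rose (adjusted p = 0.0721), with nt5c2l1 at -0.91 ± 0.13, and of 6 pigment genes 2 fell and 1 rose (adjusted p = 0.256), with the purine enzyme gart at -1.20 ± 0.14. Of 29 crest and cartilage genes 5 fell and 3 rose (adjusted p = 0.802), col2a1a falling (-1.04 ± 0.15) and msx2b rising (0.82 ± 0.12). Of 30 somite genes 7 rose and 2 fell (adjusted p = 0.306), including the myogenic factor myf5 (0.64 ± 0.16). Immediate early genes rose in 5 of 24 and fell in 2 (adjusted p = 0.159), with klf2a at 0.92 ± 0.16, and inflammation genes rose in 3 of 25 and fell in 2 (adjusted p = 0.159), with the complement gene c3a.1 at -1.37 ± 0.17. Cell cycle genes rose in 2 of 41 and fell in 1 (adjusted p = 0.159), histone genes rose in 1 of 36 and fell in 1 (0.646), and monoaminergic genes rose in 2 of 11 and fell in 2 (0.927). The p53 and ribosomal lists had 0 of 28 and 0 of 72 genes passing (adjusted p = 0.559 and 0.275), and the heart muscle, endothelium and eye lists had under 5 measured members.

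The mutant effect in numbers 4 to 6 leaned toward the 12-somite profile, with a mean slope of 0.193 (SD 0.0502 over 3 splits of the wild-type arrays) on the difference between 12-somite controls and wild type, against 0.0546 (SD 0.0116) for the injection. Normalization of the arrays is argued against, since 97.2% of the slope remained with the values as deposited. Slower development of the mutants is a candidate explanation that cannot be told apart from a difference in material, because the 12-somite and 36 h samples differ in both, and the 200 probe sets highest at 12 somites lay only 0.101 above the median of all probe sets (0.125, 0.118 and 0.0603 by split), while the 200 highest in the wild type had a median mutant effect of -0.904. Loss of transcripts of the listed tissues alone stays open too. The slope kept 81.8% without the listed genes (84.2%, 83.9% and 77.4% by split), but the lists hold few of the called probe sets. Of the 2059 called ones that were also tested across both array sets, 1732 lie outside the lists. For the falling cell cycle and progenitor genes, 25 of 44 were lower at 12 somites than in the wild type, 9 of 22 and 16 of 22, which decides neither way.

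Other splits of the same arrays were fitted in the same way. For all 10 brain arrays 2 of 100 drawn splits gave at least the 24 calls of the real one, so chance can be excluded at a share of 0.05 only if arrays may be exchanged across their label numbers. The other of these splits gave 7423, and it is the split by array set, numbers 1 to 3 against 4 to 6, which points to a structure of the samples, and the value with the set as a block was 1425. With the set as a block 1 of 80 splits, the real one, gave as many as 1425, the highest other being 628, so chance can be excluded on the same condition. Of these splits 13 and 16 part all 4 same-numbered pairs as the real one does, with 0 and 628 as the highest other, and they are too few for a share under 0.05, while the others keep at least 1 pair together. For numbers 4 to 6 the real split gave 2119 and the highest other 0, 1 of 10 splits, which are too few for a share under 0.05. The same holds for the injection, 1 of 10, where the real split gave 1223 and the highest other 0.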
